A study of Mus musculus with 6 samples.

How the data were processed

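RNA from whole mouse lung (C57BL/6 background) was sequenced in 6 libraries, 3 from lungs given saline through the trachea and 3 from lungs given lipopolysaccharide (LPS), the cell wall component of Gram-negative bacteria that drives acute lung inflammation. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a directional kit. Per the submitters' processing notes, reads were aligned with TopHat to the mm10 build of the mouse genome. The counting tool, the gene annotation and the scaling between libraries are not given in the sources used here.

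Each library has 1 table with a gene symbol and a value, and the values the authors deposited are on a log2 scale. That unit was read from the values, which are at least 0, are not whole, reach 17.3 and hold exact zeros, as log2 of an expression value plus 1 would. Low values, multiplied by transcript length, gather in steps. Over genes with 1 transcript the fullest bin held 52 to 95 genes in each library, against at most 41 with the lengths shuffled, so the value before the log appears to be scaled by gene length. No counts were analysed here, so depth is unknown and no count-based interval or detection limit is given. The tables differ in their low range. Each saline table holds 3869 exact zeros, for the same genes, and 1505 to 1936 values above 0 but under 0.01. Values above 0 but under 0.003 stand in nearly fixed ratios between the saline libraries: of 1045 genes in that range in both saline 1 and saline 2, 99.1% lay within 1% of the median ratio. The LPS tables hold 5117 to 6223 exact zeros and 11 to 24 such tiny values. The step that made this difference is not given in the sources used here. The difference follows the groups, so effects of how the tables were made cannot be told apart from those of treatment. The table of LPS 3 ends early, so that 4484 of the 23183 genes (19.3%) have no value in it, and 18699 genes have a value in all 6 libraries. Among genes with a deposited value of 1 or above in both libraries of a pair, 0 had identical values in any pair.

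Libraries were grouped by treatment, on which title and treatment field agree. The labels disagree on genotype. All 6 titles and the design text name wild-type mice, whereas the genotype field of LPS 1 and LPS 2 names a knockout of Lcn2 and that of LPS 3 a knockout of Lcn4. No library was moved or left out for this reason, and the comparison is between libraries labelled LPS and libraries labelled saline. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

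The comparison was fitted with limma 3.58.1 in R 4.3.3, with a trend of the variance on mean expression, on the deposited values, that is on log2(value + 1). Fold changes on this scale understate the change of genes with low values. Genes were kept where at least 3 libraries had a value of 1 or above before the log. This kept 13116 genes, of which 10295 had 3 LPS values and 2821 had 2. P-values were adjusted with the Benjamini-Hochberg method and the threshold was 0.05. The design written before the data were examined held a branch for counts and a branch for normalized values, and the second was used, without a further log. Data were simulated for the comparison of LPS with saline (5 simulations of 13116 genes). In each, 200 drawn genes were changed, and the remaining members of the chemokine list were raised 2-fold. The fit recovered 48.7% of genes changed 2-fold, these chemokine genes included, and 93.0% of genes changed 4-fold. Of its calls 4.09% were false, and 0 of 170 tests of unchanged gene lists were called. The simulated noise was independent between genes, so the false calls do not cover genes that vary together, nor the list result lists whose members do. Far fewer genes were changed than the 50.1% called in the real data, so the recovered and false shares may not carry over. In the real data the estimated correlation within a list reached 0.867, in the interferon and cardiac lists.

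Gene lists were fixed before the data were examined: 36 lists of cell type markers, pathways and tissues that could be present in a lung piece. For each, the members past the threshold were counted over all genes tested and adjusted over the list alone. Set tests were run with camera (preset correlation of 0.01 between genes, and with an estimated correlation) and with fry, on the 10295 genes with 6 values, for the 33 lists with at least 3 such members, with Benjamini-Hochberg adjustment over the lists. The genes named were set by a rule. It took Lcn2 and its receptors Slc22a17 and Lrp2, then the 10 largest changes in each direction among protein-coding genes past the threshold. Those 20 had a value in all 6 libraries, LPS values all on one side of the saline values and a mean in the upper part, split at the median, of the tested genes. Up to 4 called members of each list were added, or the 2 with the highest mean where none was called, and some genes that the rule takes are not reported here. Predicted gene models and single antigen receptor segments were not named among the 20. Some genes named outside the rule, among them list members that did not pass or went against their list, were chosen after their values were seen. Not all of them are marked so where they appear. The adipocyte and tracheobronchial secretory lists were also made after the data were seen.

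Gene positions are from GENCODE M21 for the same build of the mouse genome, in which 22110 of the 23183 symbols (95.4%) matched a single gene. Transcript lengths were available for 96.4% of tested genes. Principal components used the 2000 most variable genes. Alternatives changed the scaling, the filter on low values, the variance trend, the pseudocount, the threshold, the block by replicate number and the libraries used. After the data were seen, 4 more were added: genes with 6 values only, saline 1 and 3 against LPS 1 and 2, libraries scaled to the same sum of values before the log, and removal of each library's trend with transcript length. Tables were joined and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.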

Results

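Gene expression was measured by RNA sequencing in lung tissue of mice given saline or LPS through the trachea, with 3 libraries in each group. Values are log2(expression value + 1) as deposited, and differences are LPS minus saline on that log2 scale. Library depth is unknown from the tables. Libraries were alike within groups and different between them: Pearson correlations across 10295 genes, which are not independent replicates, were 0.964 to 0.975 within saline, 0.984 to 0.988 within LPS and 0.824 to 0.932 between the groups. The first principal component held 89.8% of the variance of the 2000 most variable genes and separated the groups.

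The series concerns lipocalin-2, the secreted protein encoded by Lcn2 that binds bacterial iron carriers and is released by neutrophils and epithelium. Lcn2 (chromosome 2, 32384633 to 32388252, minus strand, mm10) was among the most abundant transcripts of every LPS library, with values of 13.60, 13.29 and 13.82 and at most 4 of 18699 genes above it. In saline the values were 8.20, 11.28 and 10.11. The mean was 13.57 ± 0.27 (SD, n = 3) in LPS and 9.86 ± 1.55 (SD, n = 3) in saline, a difference of 3.71 (SE 0.64; adjusted p = 0.00162, limma with Benjamini-Hochberg adjustment) or 13.1-fold. LPS 1 and LPS 2 are the libraries labelled as Lcn2 knockouts in the genotype field, and their high Lcn2 RNA goes against that label, while their titles name wild-type mice. If the genotype field were right, treatment and genotype could not be told apart in any of the differences given here. The lipocalin-2 receptor genes were both lower in LPS, and both had low values. Slc22a17 was 1.05 to 1.15 in LPS and 1.52 to 2.06 in saline, and Lrp2 0.83 to 1.05 and 2.32 to 3.15. Slc22a17 (chromosome 14, 54906304 to 54913132) fell by 0.72 (SE 0.17; limma adjusted p = 0.00692), a call that ended with quantile normalization (-0.36). Lrp2, which encodes the endocytic receptor megalin (chromosome 2, 69424340 to 69586065), fell by 1.72 (SE 0.21; limma adjusted p = 0.000335).

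The lungs of the libraries labelled LPS had higher RNA levels for neutrophil-attracting chemokines, acute phase proteins, metallothioneins and interleukin-6 than those labelled saline. Among genes with a value in all 6 libraries and a mean above the median of the tested genes, the largest increases were in Cxcl2 (7.17, SE 0.66; chromosome 5, 90903871 to 90905938), a ligand of the neutrophil receptor CXCR2, and Ccl20 (7.14, SE 0.43; chromosome 1, 83116766 to 83119167), which attracts CCR6-bearing lymphocytes and dendritic cells. Next came the serum amyloid gene Saa3 (6.66, SE 0.95), the metal-binding gene Mt2 (6.51, SE 0.50), Cxcl1 (5.86, SE 0.41), Il6 (5.64, SE 0.49), Saa1 (5.61, SE 0.64), Ccl3 (5.51, SE 0.78), Ccl2 (5.39, SE 0.62) and Ccl4 (5.34, SE 0.67). The largest decreases among them were in Bpifa1 (-6.50, SE 1.32; LPS values 0.85, 1.66 and 7.17; chromosome 2, 154142880 to 154149219), an airway surface protein, and Nppa (-5.25, SE 0.97; chromosome 4, 148000722 to 148002079), the atrial natriuretic peptide of heart muscle. They were followed by the integrin gene Itga8 (-3.70, SE 0.28), Myh6 (-3.64, SE 0.67), Ogn (-3.56, SE 0.34), Clec3b (-3.13, SE 0.26), the alcohol dehydrogenase gene Adh1 (-3.13, SE 0.32), Mb (-3.10, SE 0.68), the B cell gene Ms4a1 (-3.07, SE 0.22) and the sodium channel gene Scn7a (-2.84, SE 0.26). All 20 had limma adjusted p-values of at most 0.00518 (Mb).

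**Figure D1:**
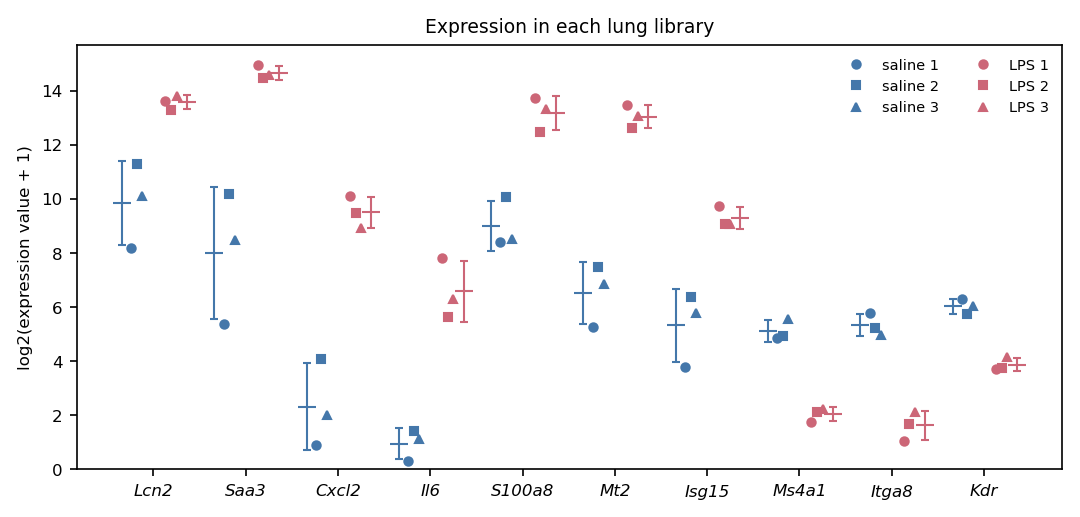
Points are the log2(expression value + 1) of 10 genes in each of the 6 lung libraries (saline in blue, LPS in red, replicates by symbol), and bars give the mean and SD of each group (n = 3). Lcn2 lies between 13.29 and 13.82 in LPS and between 8.20 and 11.28 in saline, and saline 2 has the highest saline value of Lcn2, Saa3 and Cxcl2.

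Of 13116 genes tested, 6565 (50.1%) differed between LPS and saline, 3377 higher and 3188 lower in LPS. Of these, 2378 differed at least 2-fold (1214 higher, 1164 lower), and at 4-fold or more 299 were higher and 177 lower. Without saline 2 and LPS 3 together, 5844 genes passed (3207 higher, 2637 lower). Of the genes named in this part, Timp1, Tnfaip3, Sln, Sod2, Sox17, Slc39a14, Steap4, Slc7a11 and Tnnt3 have no value in LPS 3. The balance of directions rests on the scaling and on the filter. With a mean value of at least 5, 2988 genes were called higher and 1752 lower. With every library set to the same sum of values before the log, the median of all genes moved from 0.02 to -0.67, and 798 genes were called higher and 8342 lower, so that each direction given here is relative to the scaling as deposited.

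Most chemokine, cytokine and interferon genes tested rose. Of 27 chemokine genes tested, 21 rose, 2 fell and 4 did not pass, the same counts when adjusted over the list alone; Ccl21a and Ccl8, which attract lymphocytes and monocytes, were the members that fell. Of 19 cytokine genes, 13 rose, 2 fell and 4 did not pass, again the same adjusted over the list alone, with Csf3 (5.95), the growth factor that mobilises neutrophils, Csf2 (4.70) and Il1b (4.56) beside Il6. Of 22 genes of Toll-like receptor (TLR) and NF-kB signalling, 19 rose and 0 fell (20 and 0 adjusted over the list alone), among them the LPS co-receptor gene Cd14 (3.59), the inhibitor gene Nfkbia (3.39) and Tnfaip3 (3.52). Of 26 interferon-stimulated genes, 24 rose and 0 fell on both counts, led by Isg15 (3.97), Irf7 (3.48) and Ifit1 (3.19). Of 18 acute phase and antimicrobial genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone), with Saa2 at 4.82 and Orm1 at 3.92 beside Saa1 and Saa3. Of 14 inflammasome and pyroptosis genes, 9 rose and 0 fell on both counts, among them Nlrp3 (2.48) and Mefv (2.93). The camera adjusted p was 2.43e-06 for chemokines, 1.29e-05 for cytokines, 5.70e-06 for TLR and NF-kB signalling, 4.44e-07 for interferon-stimulated genes, 5.70e-06 for acute phase genes and 0.00290 for inflammasome genes. With an estimated correlation, the adjusted p = 0.483 for the first 5 lists and adjusted p = 0.506 for inflammasome genes, and 0 of the 33 lists tested passed in that form of the test. In saline 2 the mean over the chemokine list was 4.63, against 2.88 in saline 1 and 4.01 in saline 3, and 6.63 to 6.91 in LPS.

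Most neutrophil and monocyte markers tested were higher in LPS, and 9 of 10 B cell and 6 of 10 T cell markers were lower. Of 17 neutrophil markers, 14 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 1.40e-05), including the alarmin genes S100a8 (4.18) and S100a9 (4.12) and the decoy receptor gene Il1r2 (4.81). Of 17 markers of monocytes and recruited macrophages, 12 rose and 0 fell on both counts (camera adjusted p = 0.000573), with Arg1 at 3.90, Ms4a6d at 3.30 and the Fc receptor gene Fcgr4 at 2.69. For both lists adjusted p = 0.483 with an estimated correlation. Alveolar macrophage markers went both ways, with 4 higher, 7 lower and 6 not past the test on both counts (camera adjusted p = 0.129; adjusted p = 0.607 with an estimated correlation). The eosinophil-associated ribonuclease gene Ear1 (-2.14) and Siglecf (-1.63) fell, while the lipoprotein lipase gene Lpl (2.17) rose. Of 10 B cell markers, 9 fell and 0 rose on both counts (camera adjusted p = 5.70e-06; adjusted p = 0.483 with an estimated correlation), including Cd22 (-2.50) and Cd79a (-2.32). Of 10 T cell markers, 6 fell and 0 rose on both counts (camera adjusted p = 0.0142; adjusted p = 0.506 with an estimated correlation), with Cd2 at -1.25 and Cd4 at -1.10. The T cell call ended with quantile normalization, with a mean of at least 5, with equal sums and at a threshold of 0.01. None of 8 NK cell markers passed on either count (camera adjusted p = 0.551; adjusted p = 0.846 with an estimated correlation). Their median of 0.33 turned to -0.35 with equal sums, and leaving out 1 library at a time gave camera adjusted p-values of 0.0363 (without LPS 2) to 0.804.

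Genes for leukocyte capture, matrix breakdown and oxidant production rose in part. Of 11 adhesion molecule genes, 5 rose, 1 fell and 5 did not pass on both counts (camera adjusted p = 0.0290; adjusted p = 0.512 with an estimated correlation). The endothelial selectin genes Selp (3.90) and Sele (3.56) and the integrin gene Itgam (2.78) rose, but the list's median of 0.61 turned to -0.18 with equal sums. The call ended without saline 2, without LPS 1, with saline 1 and 3 against LPS 1 and 2, with quantile normalization, with a mean of at least 5 and at a threshold of 0.01. Leaving out 1 library at a time gave camera adjusted p-values of 0.0125 (without LPS 2) to 0.120 (without LPS 1). Of 15 genes for matrix proteases and their inhibitors, 9 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00371; adjusted p = 0.483 with an estimated correlation). The members that rose included the metalloproteinase inhibitor gene Timp1 (4.78) and the neutrophil collagenase gene Mmp8 (3.33). Of 12 genes for enzymes that make reactive oxygen species (ROS) or nitric oxide, 8 rose and 1 fell on both counts (camera adjusted p = 0.0101; adjusted p = 0.483 with an estimated correlation). Subunits of the phagocyte oxidase, Cyba (1.95) and Ncf1 (1.74), rose and Nox4 fell (-2.28). Nos2, the inducible nitric oxide synthase gene, chosen after its values were seen, had a difference of -0.25 (SE 0.23; limma adjusted p = 0.398).

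Most antioxidant and glycolysis genes tested rose, and iron handling genes went both ways. Of 25 NRF2 and antioxidant genes, 19 rose and 3 fell (20 and 3 adjusted over the list alone; camera adjusted p = 0.000275; adjusted p = 0.483 with an estimated correlation), led by the metallothionein genes Mt2 and Mt1 (5.01), then Sod2 (2.78) and Gpx2 (2.43). The camera call for this list ended with quantile normalization. Of 23 iron handling genes, 10 rose and 6 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.421; adjusted p = 0.607 with an estimated correlation), and their median of 0.21 turned to -0.52 with equal sums. The haem-binding protein gene Hpx (3.17), the metal importer gene Slc39a14 (2.78), the reductase gene Steap4 (2.67) and the phagosomal metal transporter gene Slc11a1 (2.29) rose. Of 15 ferroptosis genes, 6 rose and 2 fell on both counts (camera adjusted p = 0.293; adjusted p = 0.614 with an estimated correlation), with a median of 0.10 that turned to -0.45 with equal sums. The members that rose included the ferritin gene Fth1 (2.19) and the cystine transporter gene Slc7a11 (2.40). Of 16 glycolysis and HIF genes, 12 rose and 1 fell on both counts (camera adjusted p = 0.00138; adjusted p = 0.483 with an estimated correlation), with Irg1 (4.59), which makes itaconate, and Hif1a (2.67).

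Of 10 glucocorticoid response genes, 9 rose and 0 fell on both counts (camera adjusted p = 0.000118; adjusted p = 0.408 with an estimated correlation), including Fkbp5 (2.41) and Dusp1 (2.11), and this list shares Mt1 and Mt2 with the antioxidant list. Of 13 circadian clock genes, 2 rose and 6 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.157; adjusted p = 0.614 with an estimated correlation), with Dbp at -2.77, Nr1d1 at -2.62 and Cry1 at 1.15. Of 17 genes of xenobiotic and lipid metabolism, 9 fell and 1 rose on both counts (camera adjusted p = 0.00716; adjusted p = 0.506 with an estimated correlation), with Cyp2e1 (-2.64), Aox3 (-2.54) and Fmo2 (-2.19) lowest. Of 13 cell cycle genes, 1 fell and 0 rose, and 0 passed adjusted over the list alone (camera adjusted p = 0.108; adjusted p = 0.614 with an estimated correlation). Leaving out 1 library at a time gave camera adjusted p-values of 0.000355 (lower, without saline 1) to 0.508 (without saline 3) for that list.

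**Figure D2:**
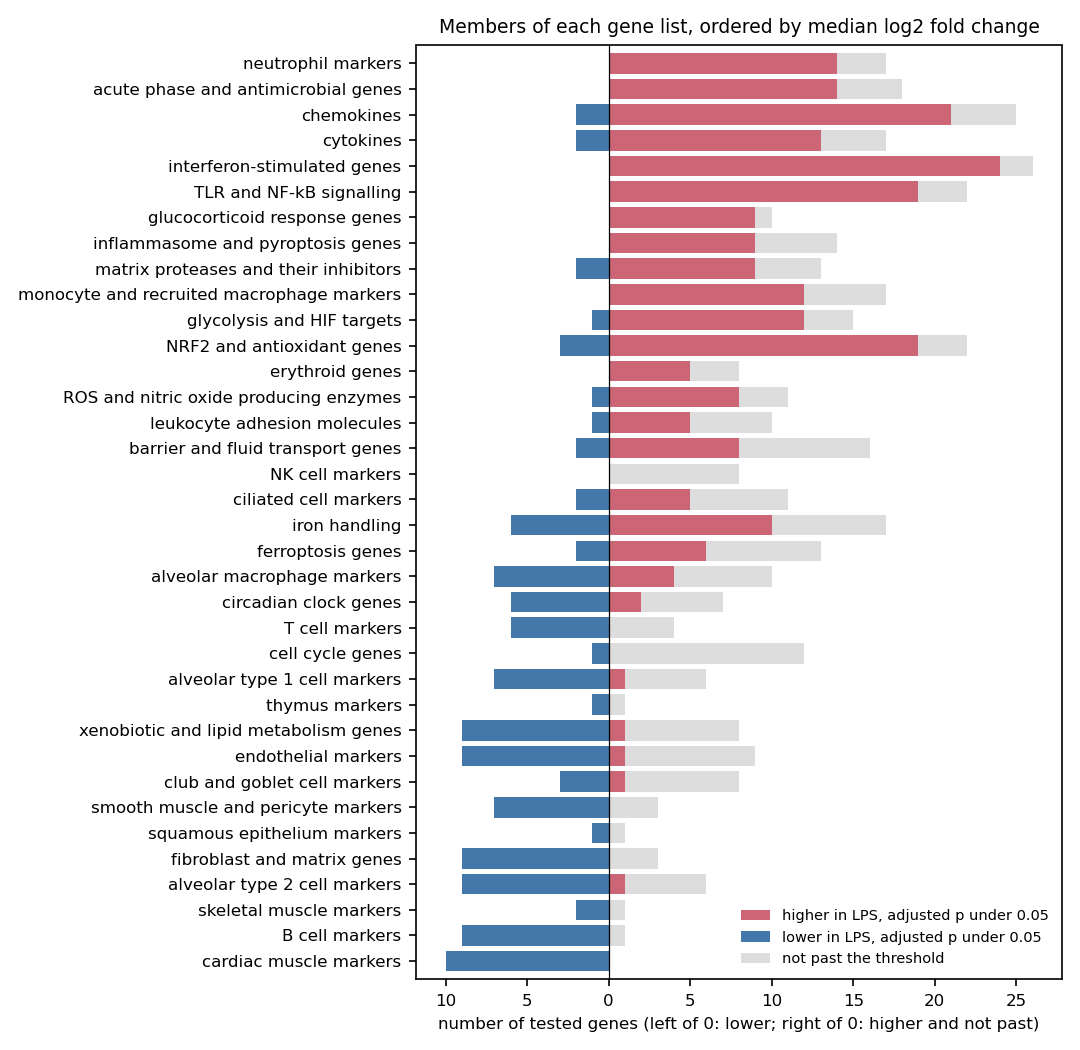
Bars count the tested members of each of the 36 gene lists (vertical axis, ordered by median log2 fold change): lower in LPS to the left of 0, higher in LPS and then not past the threshold to the right. Cardiac muscle markers had 10 of 10 lower and interferon-stimulated genes 24 of 26 higher.

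In each list of resident cells of the alveolus, its vessels and its matrix, more markers fell than rose. Of 15 alveolar type 2 cell markers, 9 fell and 1 rose on both counts (camera adjusted p = 0.000805; adjusted p = 0.483 with an estimated correlation), among them the lipid synthesis genes Fasn (-2.30) and Scd1 (-1.64) and Lpcat1 (-1.77), which makes surfactant lipid. Adipocytes also express the lipid synthesis genes, and adipocyte markers fell in the same libraries. The surfactant protein gene Sftpd rose (1.19), and Sftpc, Sftpa1, Napsa, Lamp3 and Nkx2-1 did not pass. Of 13 alveolar type 1 cell markers, 7 fell and 1 rose on both counts (camera adjusted p = 0.172; adjusted p = 0.614 with an estimated correlation), with Rtkn2 at -2.02 and the basement membrane collagen gene Col4a3 at -1.31. Scnn1g rose (0.64), and Ager, Hopx, Pdpn, Aqp5 and Igfbp2 did not pass. Of 18 endothelial markers, 9 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.0262; adjusted p = 0.483 with an estimated correlation). Those that fell included Aplnr (-2.60), Ptprb (-2.21) and the VEGF receptor gene Kdr (-2.17). Robo4 rose (0.96), and Pecam1, Cdh5, Cldn5, Esam, Sox17, Car4, Gpihbp1 and Emcn did not pass over all genes tested. Leaving out 1 library at a time gave camera adjusted p-values of 0.00220 (without LPS 3) to 0.0653 (without saline 2) for the endothelial list, whose call also ended without a filter on low values and at a threshold of 0.01. Of 12 fibroblast and matrix genes, 9 fell and 0 rose on both counts (camera adjusted p = 0.00135), with Inmt at -2.25, Npnt at -2.24 and Col1a1 at -1.87. Of 10 smooth muscle and pericyte markers, 7 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 0.00526), with Notch3 at -1.89 and Myh11 at -1.61, and this camera call ended with equal sums. For these last lists adjusted p = 0.483 with an estimated correlation.

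Airway and barrier genes moved in both directions. Of 11 club and goblet cell markers, 3 fell and 1 rose on both counts (camera adjusted p = 0.157; adjusted p = 0.614 with an estimated correlation), with Bpifa1 and the club cell enzyme gene Cyp2f2 (-1.32) lower. Leaving out 1 library at a time gave camera adjusted p-values of 0.00286 (lower, without LPS 3) to 0.307 (without LPS 1) for that list. Of 13 ciliated cell markers, 5 rose and 2 fell on both counts (camera adjusted p = 0.974; adjusted p = 0.990 with an estimated correlation). Their median of 0.29 and mean of 0.18 were above 0 while the set test, on 10 members with 6 values, pointed down, and the median turned to -0.49 with equal sums. Sec14l3 (-1.34) fell and Ccdc113 (1.09) rose, a call that ended with equal sums (0.32). Of 18 barrier and fluid transport genes, 8 rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.149; adjusted p = 0.607 with an estimated correlation), and the median of 0.39 turned to -0.14 with quantile normalization and to -0.40 with equal sums. The water channel gene Aqp1 fell (-0.98) and the claudin gene Cldn4 rose (1.05), a call that ended with equal sums (0.44).

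Markers of tissues that can come with a lung piece also differed. All 10 cardiac muscle markers tested fell on both counts (camera adjusted p = 0.00323; adjusted p = 0.483 with an estimated correlation), with Nppa, Myh6, Sln (-3.33) and Pln (-3.28) lowest. The camera call ended with equal sums. The mean of the 7 with a value in all 6 libraries differed within groups, at 7.24, 5.60 and 4.34 in saline and 2.04, 2.72 and 3.40 in LPS. Of 3 skeletal muscle markers, 2 fell on both counts (Ckm -2.34; Tnnt3 -1.50, not past the test without LPS 2, which leaves it 1 LPS value). Without a filter on low values the calls of Sln, Ckm and Tnnt3 ended. Of 2 thymus markers, 1 fell (2 adjusted over the list alone; Cd1d1 -0.86), and of 2 squamous epithelium markers, 1 fell on both counts (Krt15 -1.94). Of 8 erythroid genes, 5 rose and 0 fell on both counts (camera adjusted p = 0.0291; adjusted p = 0.506 with an estimated correlation), led by the globin gene Hba-a2 (3.20), whose reads cannot be fully told apart from those of its near-identical copy Hba-a1 (1.26). The call of Hba-a1 ended without saline 3, with quantile normalization (0.20), with equal sums (0.46) and with the length trend removed (0.58). The call of the erythroid list ended without saline 3, without LPS 2, with quantile normalization, with a mean of at least 5, with the length trend removed and at a threshold of 0.01. Leaving out 1 library at a time gave camera adjusted p-values of 0.0175 (without saline 1) to 0.0898 (without saline 3).

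**Figure D3:**
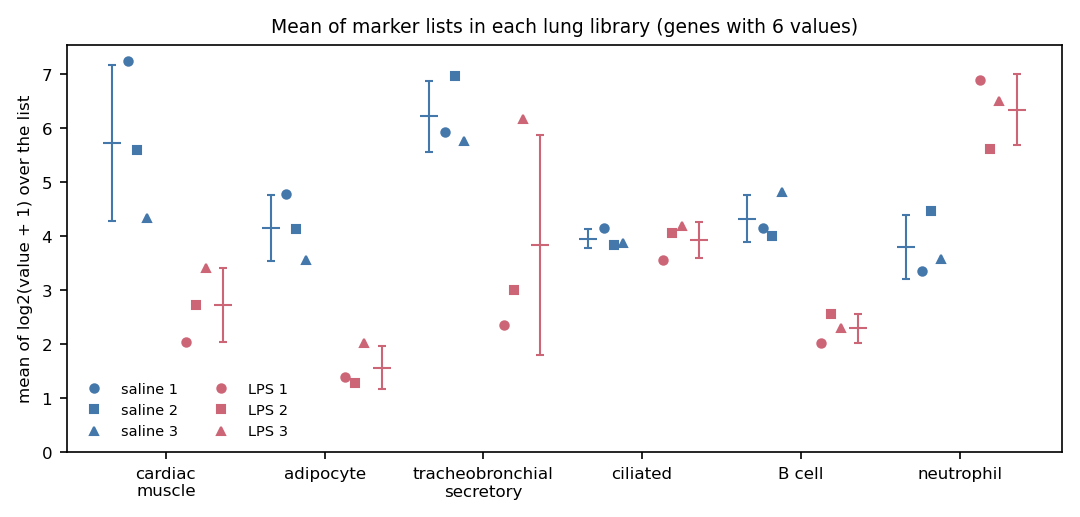
Points are the mean of log2(value + 1), over the members with a value in all 6 libraries, of 6 marker lists in each of the 6 lung libraries (saline in blue, LPS in red, replicates by symbol), with the mean and SD of each group (n = 3). Cardiac markers lie between 4.34 and 7.24 in saline and between 2.04 and 3.40 in LPS, and LPS 3 stands at 6.16 for the tracheobronchial secretory list against 2.36 in LPS 1.

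Differences also followed transcript length. The median difference was 0.45 in the fifth of tested genes with the shortest transcripts (126 to 1884 nt) and -0.39 in the fifth with the longest (5161 to 123179 nt). The same comparison between saline 2 and saline 1 gave 0.29 and -0.28. With each library's trend removed, 5920 genes passed (3011 higher, 2909 lower), and 76.6% of the called genes with a known length kept their call and direction.

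**Figure D4:**
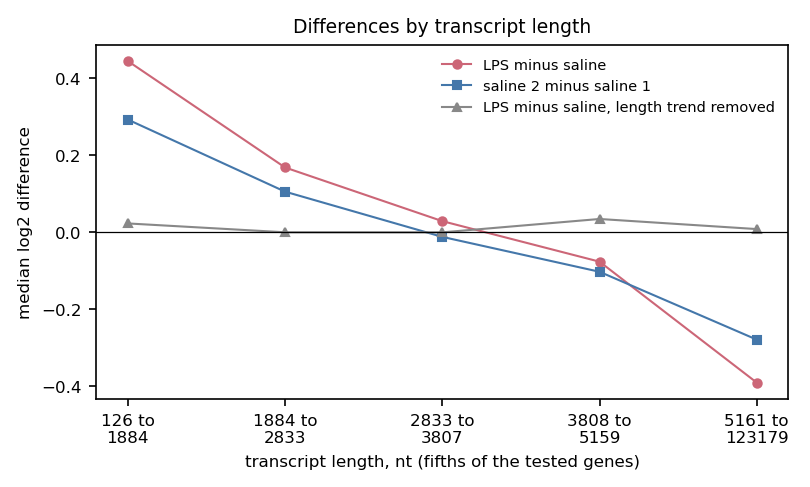
Lines give the median log2 difference of tested genes (vertical axis) in 5 groups of transcript length in nt (horizontal axis), for LPS minus saline, for saline 2 minus saline 1 and for LPS minus saline with each library's length trend removed. The median falls from 0.45 to -0.39 for LPS minus saline and from 0.29 to -0.28 for saline 2 minus saline 1.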

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

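The alternatives that use the same sum of values, a removed length trend, genes with 6 values, or saline 1 and 3 against LPS 1 and 2 were chosen after the data were seen; where no reason is given below, the cause was not tested. Lcn2 was higher in LPS under all 17 alternatives run on it (2.48 to 4.42; limma adjusted p 0.000442 to 0.0235). The number of genes past the threshold was 4037 to 9140 over 18 alternatives. At an adjusted p under 0.01, a stricter threshold by construction, 4037 genes passed (2033 higher, 2004 lower). With a mean value of at least 5, which tests fewer genes, 2988 were higher and 1752 lower (at least 2-fold: 1093 and 670). With equal sums, 798 were higher and 8342 lower, and 4414 differed at least 2-fold (410 higher, 4004 lower). Quantile normalization kept 68.1% of the calls and equal sums 60.7%, with 31 calls turned. The values gave no sign that the replicate numbers pair the libraries, though 3 libraries in each group cannot exclude it. Deviations of libraries with the same number correlated at -0.23, -0.08 and -0.25, and no library correlated best with its own number. The fit with the replicate number as a block called 5417 genes. Single genes changed direction in Hbb-b1 with quantile normalization (-0.043), in Gzma (-0.19), Nkg7 (-0.45) and Gabrp (-0.17) with equal sums, and in Nkg7 with the length trend removed (-0.27).

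For the gene lists, camera adjusted p-values changed sides or the list changed direction as follows. With an estimated correlation 0 lists passed, at 0.483, 0.506 (T cell, erythroid, inflammasome, xenobiotic), 0.512 (adhesion) and 0.408 (glucocorticoid). With fry, which tests a list against no change and not against other genes as camera does, the ferroptosis list passed (0.0435). With quantile normalization alveolar macrophage (0.0279), alveolar type 1 (0.00178) and club cell lists (0.0213) passed, and T cell (0.0901), erythroid (0.363), NRF2 (0.0650) and adhesion lists (0.108) did not, while ciliated (0.996) and barrier lists (0.474) turned. With no filter the barrier list passed (0.0416), the endothelial list did not (0.0591) and the ciliated list turned (0.787). With a mean of at least 5 the iron list passed (0.0361), T cell (0.0631), erythroid (0.101) and adhesion lists (0.0851) did not, and the ciliated list turned (0.608). Under the 0.01 threshold T cell (0.0142), endothelial (0.0262), erythroid (0.0291), ROS (0.0101) and adhesion lists (0.0290) did not pass. With saline 1 and 3 against LPS 1 and 2, alveolar type 1 (0.0301), club cell (0.00744) and circadian lists (0.0337) passed, the adhesion list did not (0.0505) and the ciliated list turned (0.631). With equal sums T cell (0.0713), smooth muscle (0.0644) and cardiac lists (0.132) did not pass and the ciliated list turned (0.841). With the length trend removed the alveolar macrophage list passed (0.0328), the erythroid list did not (0.373), and NK (0.759) and ciliated lists (0.855) turned. Leaving out 1 library at a time gave 0.0363 to 0.804 for NK, 0.00286 to 0.307 for club cell, 0.436 to 0.9996 for ciliated, 0.00220 to 0.0653 for endothelial, 0.0175 to 0.0898 for erythroid, 0.0125 to 0.120 for adhesion and 0.000355 to 0.508 for cell cycle lists. The ciliated list turned without saline 1, saline 3, LPS 1 or LPS 3, and the NK list without LPS 1. The alternatives written for counts were not run, as no counts were analysed here. Depth is unknown, so what it limits was not examined.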

Other observations

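The tests of a mixed library, of swapped labels, of cardiac tissue and of the length trend in parts by fold size were chosen after the results were seen. Most ribosomal protein genes, a group picked after the data were seen, were higher. Of 78 ribosomal protein genes, 68 were higher and 0 lower in LPS, with a median of 0.94, which was 0.50 with the length trend removed and 0.16 with equal sums; 900 other short and abundant genes had a median of 0.72. Adipocyte markers, a list made after the data were seen, were lower: 7 of 8 fell and 0 rose, the same counts adjusted over the list alone, with Car3 at -4.83, the complement factor gene Cfd at -4.65 and the adiponectin gene Adipoq at -3.18. Their mean was 4.77, 4.13 and 3.56 in saline and 1.39, 1.29 and 2.02 in LPS, and the list shares Fabp4 with the alveolar macrophage markers.

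Secretory genes of the larger airways separated LPS 3 from the other LPS libraries. Of 8 genes in this list, also made after the data were seen, 3 fell and 0 rose, the same adjusted over the list alone (Bpifa1 -6.50, Tff2 -2.48, Bpifb1 -2.19). Tff2 has no value in LPS 3, and the call of Bpifb1 ended without saline 2 and without a filter on low values. Bpifa1 was 0.85 and 1.66 in LPS 1 and LPS 2 but 7.17 in LPS 3. Scgb3a1 was 3.60, 4.80 and 9.91 and Reg3g 2.79, 4.44 and 8.53 in the same order, while Scgb1a1, the main club cell transcript, was 17.19, 17.32 and 17.30. Among genes chosen after their values were seen, Insl3 was at most 0.05 in saline and 2.82 to 3.50 in LPS. The pseudogenes Gm7367 and Oaz1-ps were listed at 0 in all LPS libraries against 3.89 to 4.25 and 6.87 to 7.95 in saline. As the tables of the 2 groups differ in their low range, a difference in processing cannot be told apart from treatment for these pseudogenes. Clca1 was 0.22, 1.32 and 4.64 in saline 1, 2 and 3, and Filip1l was 0.03 in saline 2 but 5.04 to 5.37 in the other 5 libraries.

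The 6 libraries can be split into 3 and 3 in 10 ways. The real split gave 6565 genes past the threshold, the highest of the other splits gave 1, and 1 of the 10 splits gave as many as the real one; with 10 splits the share cannot fall under 0.1.

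Short transcripts were higher and long transcripts lower in LPS. A difference by expression level is argued against as the whole cause. Within each of 5 groups by mean expression the shortest transcripts exceeded the longest by at least 0.54. The difference also rose with expression itself, with medians from -0.32 in the lowest of these groups to 0.52 in the highest. Removing each library's length trend kept 97.0% of the called genes that differ at least 2-fold. The trend removed was itself smaller than 2-fold (medians 0.45 to -0.39), which argues against it as the whole cause of those. With a trend of that size most of those calls had to stay, so the 97.0% adds little. Of all called genes 76.6% were kept, which does not decide the question for them as a whole. Of those under 2-fold 64.9% were kept. For the genes under 2-fold a length bias and a treatment effect cannot be told apart, as short and long genes may also respond differently. Saline 2 minus saline 1 showed a trend of the same direction (0.29 to -0.28).

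Saline 2 had higher inflammatory gene values than saline 1. Saa3 was 5.36, 10.19 and 8.48 in saline 1, 2 and 3. RNA of an LPS lung mixed into saline 2 as its only difference from saline 1 is argued against. The share needed ran from 1.59% to 21.5% (10th to 90th percentile, ratio 13.5, median 9.36%), where mixing alone needs about 1 value. Shares worked out for saline 3 also differed between genes (S100a8 0.28%, Retnla 30.5%). Mixing beside other differences between the saline samples is not decided, as the saline 2 values without mixing are unknown. These shares are of 72 called genes with an LPS mean of at least 100 before the log and a saline 1 value of at most 10% of it. A swap of labels is argued against by the position of saline 2, at a median of 0.24 between the other saline libraries (0) and the LPS mean (1) over the 2000 most variable genes, chosen without labels. A difference between the saline samples, such as inflammation or response to instillation, stays open and was not tested.

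Cardiac muscle genes were lower in LPS. Different amounts of cardiac tissue or pulmonary vein muscle in the lung pieces are a candidate explanation: the same 10 genes moved together between saline 1 and saline 3 (median 2.83, interquartile range 0.25), where treatment does not differ. Smooth muscle and pericyte genes differed by 0.64 between these libraries, so muscle of all kinds did not move by the same log2 amount. Lung has smooth muscle of its own, so added muscle tissue would move these genes less on a log scale. The test therefore cannot decide whether muscle of all kinds came together. A smaller amount of other muscle moving with cardiac muscle stays open, and skeletal muscle genes were not part of this test. An effect of LPS on cardiac genes stays open, since all 3 LPS libraries lie below all 3 saline libraries in the mean of the 7 list members with a value in every library.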
